A study of Homo sapiens with 4 samples.

How the data were processed

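RNA of 2 cell lines, LNCaP and DLD1, each carrying a PYCARD gene under tetracycline control, was hybridised to 4 one-colour Agilent arrays of the 4x44K design, 1 array for each of 4 groups (each line without tetracycline and with 1 µg/ml for 4 days). Groups were taken from the labels alone. The 4 arrays lay on 1 slide, so no slide effect could be separated, and array position goes with group. The deposited scanner files give the intensity of each spot, already background-subtracted by the scanner software as a processed signal, per the file headers. The software is Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 9.5.1 per the submitters' processing notes. The array design's annotation is hg19, per the file headers. The value table deposited for the series, also in intensity, held 44495 spots on a linear scale without centring: all 177980 of its values equalled the processed signal within a relative tolerance of 1e-05. Its column medians were 69.8, 47.9, 45.6 and 51.8 for LNCaP without, LNCaP with, DLD1 without and DLD1 with tetracycline.

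Each array held 43118 non-control spots, and control spots were left out. Spots marked as outliers by the scanner software numbered 397, 355, 264 and 259 in the same order of arrays and were dropped. The processed signal was put on the log2 scale relative to the array's 75th percentile, which was 1155, 713, 705 and 750.4. Repeated spots of a probe were averaged on the log2 scale, and 999 probes had 10 spots each. Of 34127 probes, 51 had every spot of an array dropped and 34076 were kept. Probes carried a RefSeq accession in 27310 cases, and 25383 of these (93.1%) were matched to a symbol through a table of the GRCh38.p14 assembly, which was used for names and for which genes neighbour each other, with no coordinates taken. The remaining 8693 probes without a symbol were left out, and 19458 genes remained, 14542 with 1 probe and 4916 with more, of which the brightest probe stood for the gene. Brightest and second probes of a gene had log2 differences correlated at r of 0.412 over 3011 genes in LNCaP and 0.495 over 3030 genes in DLD1, across genes, which are not independent replicates. Among genes past 2-fold, the second probe had the same direction in 26 of 32 cases in LNCaP and in 23 of 27 in DLD1, but reached 1.5-fold in that direction in only 17 and 16 of them. Genes on the Y chromosome and XIST were left out of the genes named, but not of the counts, the correlation or the fits.

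A gene was measured in a line if its probe was well above background on at least 1 of the line's arrays. Where a probe was not well above background on an array, its value was raised to the lowest signal among probes well above background there, or kept if higher, and folds against it are lower bounds, written as at least N-fold. Spot error came from the repeated spots and, for a log2 difference, was 0.27 for dim probes, 0.11 for middle ones and 0.08 for bright ones. With 1 array per group, genes within a line were counted by size alone, at 2-fold. The effect of tetracycline common to both lines and the difference between lines were fitted with limma 3.58.1 in R 4.3.3, in an additive model of line and tetracycline with 1 residual degree of freedom, lmFit, eBayes and Benjamini-Hochberg adjustment, over 14133 genes well above background on at least 2 arrays. For these fits 1 floor, the highest of the 4, was used on all arrays, because separate floors gave dim genes differences of their own. That choice was made after first results had been seen, and separate floors are among the alternatives. Folds written as at least N-fold between the lines were computed with each array's own floor, outside the fit, and their adjusted p comes from the fit.

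The groups, the designs, the rule for naming genes, the settings to be varied and 24 gene lists were fixed before the data were examined. The lists were inflammasome, NF-kB targets, interferon-stimulated genes, antigen presentation, p53 targets, apoptosis regulators, androgen response, cell cycle, ATF4 targets, unfolded protein response, nuclear oxidative phosphorylation, mitochondrial ribosome, glycolysis and hypoxia, cholesterol synthesis, Wnt targets, immediate early genes, heat shock, metallothioneins, NRF2 targets, epithelial and mesenchymal genes, and prostate, colorectal, leukocyte and stromal markers. A list's value is the median log2 difference of its measured members minus that of all genes, set against 10000 random lists of the same size matched on mean signal in 20 bins. The percentile describes these arrays and is no test. Members past 1.5-fold were counted.

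The genes named were PYCARD and, per line, the 12 largest rises and 12 largest falls among genes well above background on both arrays, changed at least 2-fold with every other measured probe in the same direction, and the 3 largest lower bounds each way. Between the lines they were the 10 with the largest smaller change in a shared direction, the 5 in each opposite direction, and the 10 largest differences each way between LNCaP and DLD1. Members of a fixed list were named with it. Of the genes this rule picks, 3 are not reported here, among them genes whose direction changed with the choice of probe, and no others were put in their place.

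Both fits and lists were tested on simulated data. With known common changes planted among 14133 genes, 50 genes per size, limma recovered 46 of 50 at log2 1 and 50 of 50 at log2 2. It recovered 50 of 50 at log2 3 and 39 of 50 at log2 -1. The 32 false calls were a larger share of the calls than an adjusted p of 0.05 allows on average. The simulated noise was normal with a single spread per brightness bin, so recovery can be lower on the real arrays. Of 100 lists of 30 genes with no planted shift, 2 lay above and 1 below the middle 95% in each line. With a shift of 0.15 there were 72 above it in LNCaP and 66 in DLD1. The simulated genes varied independently of each other, so these rates do not cover real lists whose genes vary together.

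Alternatives were normexp background correction (offset 50) with quantile normalization, run on the median spot and background signals because the files hold no mean signal column, quantile normalization alone, the percentile over probes above background on all arrays, loess on mean signal (span 0.4), scaling to 8 spike-in probes, the deposited value table, the mean of all probes, stricter and no filters, other fold thresholds, trended and robust eBayes and the model without the line. Spike-in signals were graded on every array, with R² of 0.978, 0.984, 0.982 and 0.982. After the data were seen, more alternatives were added: separate floors, counts within a line over genes above the median signal, and leaving out clustered spots. A clustered spot is a dim spot (signal under 100) with at least 2 neighbouring dim spots that changed in the same direction. The clustered spot itself need not have changed. The definition was chosen after the clusters had been seen and refined once after it was seen which named genes it marked. For a probe with repeated spots, the median number of changed neighbours over its spots was used. Lists of members above background on both arrays were added too. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.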

Results

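RNA from 2 cancer cell lines was measured on 4 one-colour expression arrays, 1 array for each of 4 groups. LNCaP is an androgen-responsive prostate cancer line and DLD1 is a colorectal cancer line. Each had been given a PYCARD gene under tetracycline control, and each was grown either without the drug or with 1 µg/ml of it for 4 days. PYCARD, also called ASC, is the adaptor protein that links inflammasome sensors to caspase-1. The arrays had 43118 spots for transcripts, of which 63.7% (LNCaP without tetracycline), 60.9% (LNCaP with), 60.5% (DLD1 without) and 63.0% (DLD1 with) were well above background, and 0 were saturated. With 1 array per group there is no spread between replicates, so differences within a line are given by size, without a p-value. The number of arrays limits their precision. Errors printed after ± are spot errors on the log2 scale. They are the typical spread between repeated spots of the 999 probes with 10 spots, at the gene's brightness, scaled to its number of spots. The gene's own spread was not used. These errors cover the printing and scanning of an array, not the cultures.

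The first comparison was whether the placed gene responded to the drug. PYCARD (NM_013258, 1 probe) was 11.2-fold higher with tetracycline in LNCaP, at log2 3.48 ± 0.08, and 6.40-fold higher in DLD1, at log2 2.68 ± 0.08. The background-subtracted signal went from 25522 to 176294 in LNCaP and from 6968 to 47496 in DLD1. PYCARD was thus well above background in both lines without the drug. The probe was among the brightest on the arrays after treatment, with 11 of 34076 probes brighter in LNCaP and 182 in DLD1. The related gene PYDC1 (NM_152901), a pyrin-domain protein similar in sequence to the pyrin domain of PYCARD, was also higher: 86.6-fold in LNCaP (log2 6.44 ± 0.13) and 10.4-fold in DLD1 (log2 3.37 ± 0.15). Its signal went from 139.9 to 7475 in LNCaP and from 82.0 to 904 in DLD1. Whether the PYDC1 probe also binds PYCARD transcript is not known from its sequence, which was not used here.

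**Figure D1:**
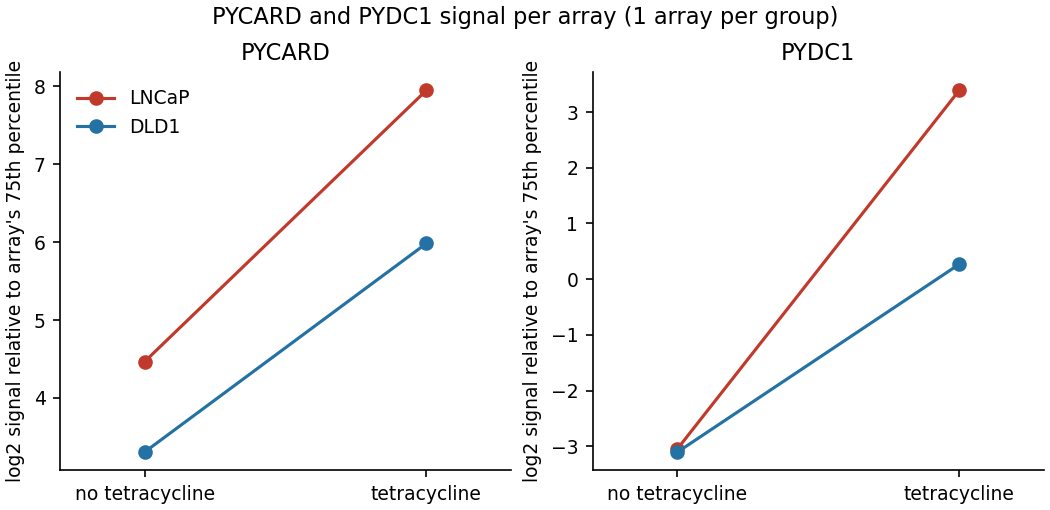
PYCARD (left) and PYDC1 (right) signal on each of the 4 arrays, as log2 relative to the array's 75th percentile, without and with tetracycline, with 1 point per array and a line joining the 2 arrays of a cell line. Both genes were higher with tetracycline in both lines, PYCARD by log2 3.48 in LNCaP and 2.68 in DLD1, and PYDC1 by 6.44 and 3.37.

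In LNCaP, tetracycline went with higher p53 target transcripts and lower cell cycle transcripts. All 30 measured p53 targets had a positive difference, of which those under 0.51 turn negative with spike-in scaling, and 17 were at least 1.5-fold higher, led by the cell cycle inhibitor CDKN1A (log2 2.03 ± 0.10), TP53I3 (1.38), the kinase PLK2 (1.27), BTG2 (1.21), the death receptor FAS (1.09) and GADD45A (1.08). MDM2, the ubiquitin ligase that limits p53, stood at 0.78 and the growth factor GDF15 at 0.91. All 43 measured cell cycle genes had a negative difference and 11 were at least 1.5-fold lower, among them KIF20A (-0.90), the mitotic kinase AURKB (-0.82), the centromere histone CENPA (-0.81) and KIF11 (-0.77). The p53 median was 0.70 above that of all genes and lay above all 10000 random lists of the same size and brightness, while the cell cycle median was -0.49 and lay below all of them.

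Other list shifts in LNCaP lay outside the middle 95% of the random lists as well. Cholesterol and lipid synthesis genes had a median of -0.21, with SC5D (-0.85), FADS2 (-0.72) and ELOVL6 (-0.60) at least 1.5-fold lower and no member as much higher. The medians of Wnt targets (-0.20), prostate markers (-0.18) and mitochondrial ribosome and translation genes (-0.13) lay below their random ranges, with few members past 1.5-fold: 0 of 18 Wnt targets, 1 of 20 prostate markers, OR51E1, lower and above background on 1 array, and 2 of 30 mitochondrial genes, MRPL12 lower (-0.70) and MTIF2 higher (0.62). Targets of NRF2, the regulator of antioxidant genes, were higher (0.19), with heme oxygenase HMOX1 at 1.41 and GPX2 at 0.84, and unfolded protein response genes stood at 0.12 with 0 members past 1.5-fold. Taken as a mean in place of a median, the unfolded protein response (0.06) and Wnt (-0.21) lists lay inside the random range, and the former also did against unmatched lists. Leukocyte markers, mostly dim here, had a median of 0.81 over 11 measured members on the same pair of arrays, with CD14 (1.23), CD79A (1.12), SPI1 (1.08) and TYROBP (0.93) among 6 higher and CORO1A lower (-0.79). Under normexp and quantile normalization the leukocyte median was 0.15.

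Over all genes, 343 of 13701 measured in LNCaP were at least 2-fold higher with tetracycline and 125 at least 2-fold lower. Of the genes well above background on both arrays, 12850 in number, 218 were higher and 43 lower, and 203 of these 261 lay in the dimmest of 4 equal bins of signal (163 higher, 40 lower). After PYDC1, the largest rises were SH2D2A (log2 4.20 ± 0.16), a T-cell adaptor, PYCARD, CCDC183-AS1 (3.33), the early-embryo gene ZSCAN4 (3.26 ± 0.23), ITGA9 (2.94), the sulfatase SULF2 (2.86 ± 0.16), COL20A1 (2.86), MISP (2.85), PRAMEF8 (2.79), ALKBH1 (2.78 ± 0.16) and PRAMEF12 (2.76). PRAMEF genes are near-copies of each other, so their probes may not tell members apart. The largest falls were WNT2B (-3.32), RPL3L (-3.30), DMXL2 (-2.35), FAM30A (-2.23), CHST10 (-2.22), ACVR2B-AS1 (-2.14), the proteoglycan SRGN, C11orf42 (-1.96), C10orf67 (-1.81), TMIGD2 (-1.79), LMF1 (-1.79) and the nucleoside kinase DCK (-1.73 ± 0.13). Spots of 9 of these 12 falls, all but FAM30A, C10orf67 and DCK, and of CCDC183-AS1 and ITGA9 among the rises, sat beside at least 2 other dim spots that had changed the same way. Genes above background on 1 of the 2 arrays gave lower bounds: ACTL6B (at least 34.2-fold), PLET1 (26.0) and ITGA4 (23.9) were higher and SYT8 (at least 21.5-fold), CYP2A13 (14.9) and SLC24A3-AS1 (14.1) lower, and all 6 sat in such clusters of changed spots. Scaling to spike-in probes moved every LNCaP difference by -0.51 and turned the split to 147 higher and 678 lower, and removing the trend with signal by loess gave 265 higher and 165 lower, so list values are given relative to the median gene. With normexp background correction and quantile normalization, 56 genes were higher and 25 lower. Without clustered spots, an alternative added after the data were seen, 292 were higher and 58 lower.

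In DLD1, tetracycline went with lower transcripts of the ATF4 programme, the response to amino acid shortage and other stress. Of 32 measured members, 31 had a negative difference and 17 were at least 1.5-fold lower, among them the stress regulator NUPR1 (log2 -2.38 ± 0.08), the hormone FGF21 (-2.10 ± 0.29), DDIT4 (-2.02 ± 0.03), an inhibitor of mTORC1, the glutathione-degrading enzyme CHAC1 (-1.48), asparagine synthetase ASNS (-1.02) and the serine synthesis enzyme PHGDH (-0.99). ATF4 itself stood at -0.64 and DDIT3 at -0.73. The list's median was -0.60 and lay below all 10000 random lists. Colorectal markers were lower too, at a median of -0.39 and with 10 of 23 members at least 1.5-fold lower and 0 higher, among them PHGR1 (-1.25), the surface antigen GPA33 (-1.15), the fatty acid binding protein FABP1 (-1.11) and NOX1 (-1.07). The intestinal transcription factor CDX2 stood at -0.57, short of 1.5-fold.

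NF-kB targets and cell cycle genes lay on the higher side in DLD1. Of 31 measured NF-kB targets, 7 were at least 1.5-fold higher and 0 lower: the cytokine LTB (2.43 ± 0.27), the feedback inhibitor TNFAIP3 (1.21), IL32 (1.19), the chemokine CCL20 (0.97), CSF2 (0.88), the apoptosis inhibitor BIRC3 (0.83) and CD83 (0.74). Their median was 0.30, above all random lists, while NFKBIA stood at -0.25 and CXCL8 at 0.28. Cell cycle genes had a median of 0.27, with 38 of 43 positive and RRM2 (0.68), the proliferation marker MKI67 (0.66) and MAD2L1 (0.62) at least 1.5-fold higher. Heat shock genes stood at 0.20, with HSPA8 (0.74), CHORDC1 (0.72) and DNAJB4 (0.67) higher, and unfolded protein response genes at 0.09, with XBP1 at -0.83. Metallothioneins stood at -0.38, with MT1F at -0.59 and 9 of 11 members negative, a family of near-copies whose probes may share signal. Prostate markers (-0.26, dim in this line), NRF2 targets (-0.17) and interferon-stimulated genes (-0.14) lay below the random range, but under loess the NRF2 median was -0.07 and the interferon median -0.11, both inside it. As means, the unfolded protein response (0.04), interferon (-0.11), NRF2 (-0.10) and prostate (-0.18) lists were inside it too.

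Over all genes, 191 of 13564 measured in DLD1 were at least 2-fold higher with tetracycline and 215 at least 2-fold lower. On both arrays above background, 97 of 12830 genes were higher and 123 lower, and the dimmest of the 4 bins held 83 and 81 of these. The largest rises were PVRIG (3.64), PYDC1, complement C3 (3.27), C16orf89 (2.98), TBC1D26 (2.78), PYCARD, the hair keratin-associated gene KRTAP3-1 (2.67 ± 0.03), SLC22A20P (2.60), TAF1L (2.48), LTB, TMEM40 (2.41) and MORN3 (2.27). Among the largest falls were NHLH1 (-4.02), ANKK1 (-3.85), the chemokine CCL19 (-3.50 ± 0.27), TCEAL2 (-3.18), ZFX (-2.96), SLC30A3 (-2.72), NUPR1, SPMIP2 (-2.33), FGF21, DDIT4 and LRRC37A6P (-1.98). Clusters of dim spots changed the same way held 7 of the 12 rises (PVRIG, C3, C16orf89, TBC1D26, SLC22A20P, TAF1L and TMEM40) and 6 of the 11 falls given here (NHLH1, ANKK1, TCEAL2, ZFX, SLC30A3 and LRRC37A6P). The lower bounds were at least 16.1-fold for ZPLD1, 13.4 for SLC38A11 and 13.2 for SEC14L3 among the rises, and at least 23.3-fold for EPHA8, 23.2 for ATRNL1 and 18.2 for PCDH7 among the falls, all 6 in such clusters. Spike-in scaling moved every DLD1 difference by 0.13 and changed the split to 265 higher and 154 lower, and normexp with quantile normalization gave 36 higher and 51 lower. Without clustered spots 147 genes were higher and 155 lower.

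**Figure D2:**
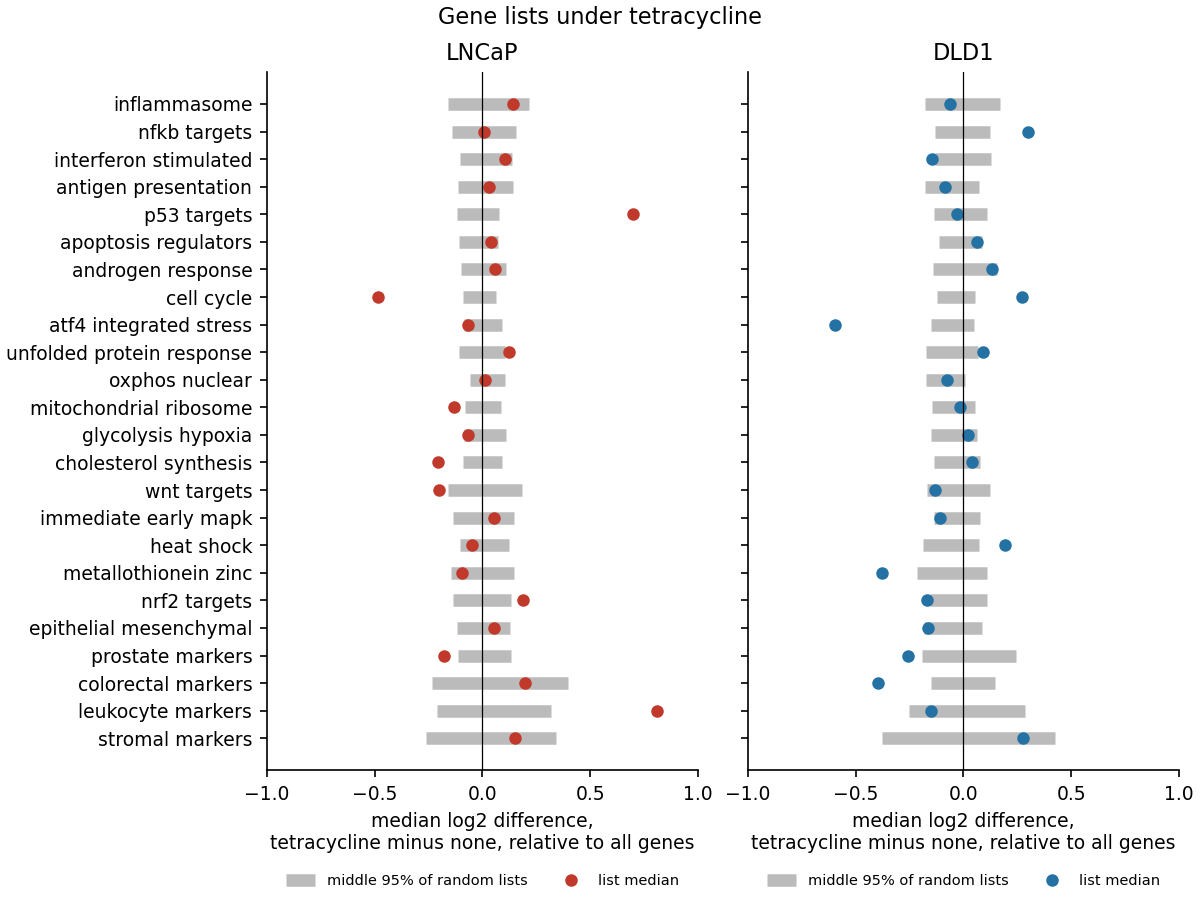
Median log2 difference, tetracycline minus none and relative to the median of all genes, for each of the 24 gene lists in LNCaP (left) and DLD1 (right), with grey bars for the middle 95% of 10000 random lists matched on size and signal. The leukocyte list at 0.81, the p53 list at 0.70 and the cell cycle list at -0.49 lie farthest out in LNCaP, and the ATF4 list at -0.60, colorectal markers at -0.39, metallothioneins at -0.38 and NF-kB targets at 0.30 in DLD1.

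**Figure D3:**
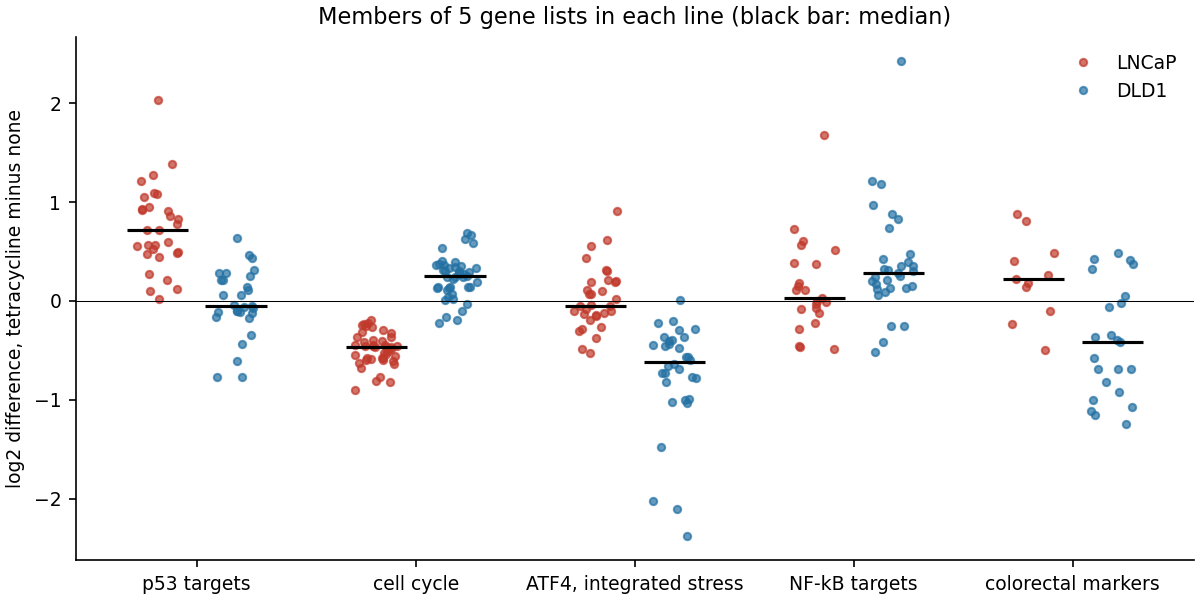
Log2 difference, tetracycline minus none, of each measured member of 5 gene lists in LNCaP (red) and DLD1 (blue), with a black bar for the median of the members. All 43 cell cycle genes were negative in LNCaP and 38 of 43 positive in DLD1.

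The remaining lists lay inside the middle 95% of their random lists by their medians. In LNCaP the medians were 0.14 for inflammasome genes, 0.01 for NF-kB targets, 0.11 for interferon-stimulated genes, 0.03 for antigen presentation, 0.04 for apoptosis regulators, 0.06 for androgen response genes, -0.07 for ATF4 targets and 0.01 for nuclear oxidative phosphorylation genes. They were -0.07 for glycolysis and hypoxia genes, 0.05 for immediate early genes, -0.05 for heat shock genes, -0.10 for metallothioneins, 0.05 for epithelial and mesenchymal genes, 0.20 for colorectal markers and 0.15 for stromal markers. In DLD1 the medians were -0.06 for inflammasome genes, -0.08 for antigen presentation, -0.03 for p53 targets, 0.06 for apoptosis regulators, 0.13 for androgen response genes, -0.07 for oxidative phosphorylation genes and -0.01 for mitochondrial ribosome genes. They were 0.02 for glycolysis and hypoxia genes, 0.04 for cholesterol synthesis, -0.13 for Wnt targets, -0.11 for immediate early genes, -0.16 for epithelial and mesenchymal genes, -0.15 for leukocyte markers and 0.28 for stromal markers. Of 23 measured NF-kB targets in LNCaP, 3 were at least 1.5-fold higher, the cytokine LIF (1.68), IL32 (0.73) and NFKBIA (0.61), and 0 lower. Among inflammasome genes other than PYCARD and PYDC1, the sensor NLRP3 (0.82 ± 0.28) and CARD8 (0.59 ± 0.22) were at least 1.5-fold higher in LNCaP. TXNIP (-0.96 ± 0.08), MEFV (-0.69 ± 0.49) and the ATP receptor P2RX7 (-0.69 ± 0.49) were lower in DLD1. The last pair are bounds with 1 array above background, and their spot errors are large beside their differences. The mean of the inflammasome list, which holds PYCARD and PYDC1, lay above the random range in both lines (0.79 and 0.23). In DLD1 the immediate early median lay below the range with loess (-0.11), the Wnt median with normexp and quantile normalization (-0.16) and the epithelial and mesenchymal median against unmatched lists (-0.16), and the cholesterol median lay above it with quantile normalization alone (0.12).

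Both lines were then compared for a shared response. PYDC1 and PYCARD were the genes with the largest change common to both, followed by HRC (log2 1.89 in LNCaP and at least 2.33 in DLD1), TRIM43 (2.41 and at least 1.81), ZPLD1, TMEM40 (1.72 and 2.41), the acute-phase gene SAA1 (at least 1.66, and 1.34), CCDC116 (at least 1.31 and 1.54), the protease inhibitor PI3 (1.24 and 1.21) and the scaffold AKAP12 (1.02 and 1.80). Lower in both were LRRC37A6P, RSPO2, AGXT, KRTAP4-8, FMO1, JAM3, ADAM11 (-0.89 and -1.01), the signalling ligand WNT5A (-0.93 and -0.84), C6 and CLPS. Of the 18 genes named here besides PYDC1 and PYCARD, TRIM43, ZPLD1, TMEM40 and LRRC37A6P sat in a cluster of changed dim spots in DLD1, and SAA1, RSPO2 and AGXT in LNCaP. Across 12327 genes measured in both lines, the log2 differences had a Pearson correlation of -0.0258 and a Spearman correlation of -0.105, over genes, which are not independent replicates. At 1.5-fold, 64 genes were higher in both lines against 21.4 for independent lists and 28 lower in both against 16.8. But opposite changes also exceeded independence (70 against 32.1 for higher in LNCaP and lower in DLD1, and 24 against 11.2 the other way). Independence takes every gene as equally likely to change, whereas most 2-fold changes in each line lay among dim genes. The excess is therefore no test of a shared response.

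A common effect of tetracycline was tested with limma, with the cell line as a block. At a Benjamini-Hochberg adjusted p below 0.05 the test called 0 of 14133 genes, and 396 had an unadjusted p below 0.05 where chance alone gives 707. As PYCARD itself was not called, the 0 calls do not show that no gene changed in both lines. PYCARD, at a log2 effect of 3.08 ± 0.25 (SE), and HRC, at 2.06 ± 0.18, shared the smallest adjusted p of limma's test, 0.946. Both were higher in 2 of 2 lines. HRC was not above background in DLD1 without tetracycline, so its effect is a lower bound and its SE rests on the floor. Adjusted over the list alone, 2 of 18 inflammasome genes passed, PYCARD and PYDC1, and 0 members of any other list did, against 0 over all genes. Under normexp and quantile normalization limma called 1 gene, PYCARD, at an adjusted p of 0.0151, and with each array's own floor, a trend and robust shrinkage, a setting added after results were seen, it called 5: PYCARD, HRC, TRIM43 and TMEM40 higher and LRRC37A6P lower. Over all settings the adjusted p of PYCARD in limma ran from 4.42e-06 to 1.

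Between the lines, the tetracycline response differed by at least 2-fold in 757 genes, 510 with the higher difference in LNCaP and 247 in DLD1. These counts used each array's own floor and hold bounds of genes above background on 1 array of a line. With tetracycline the floor went from log2 -6.43 to -5.90 in LNCaP and from -6.01 to -6.33 in DLD1. For dim genes this favours a higher difference in LNCaP. Spike-in scaling, which moved LNCaP differences by -0.51 and DLD1 differences by 0.13, was not run for this count. LCN15 (log2 1.55 in LNCaP and -1.25 in DLD1), TG (1.40 and -1.27), ELFN1 (1.16 and -1.53) and CNDP1 were higher in LNCaP and lower in DLD1. KRT13, ASAP1-IT1, LGALS7 and the centromere gene CENPI (-0.94 and 0.76) were lower in LNCaP and higher in DLD1. CNDP1 in DLD1, and KRT13 and ASAP1-IT1 in LNCaP, sat in clusters of changed dim spots. Under normexp and quantile normalization 119 genes had the higher difference in LNCaP and 49 in DLD1. The difference between the lines uses every degree of freedom of the 4 arrays and was not tested.

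The lines themselves differed in genes of their tissues of origin. Of 19 prostate markers tested, 17 were higher in LNCaP and 0 in DLD1, among them the folate hydrolase FOLH1, also called PSMA (at least 1174-fold), and the protease KLK3, also called PSA (350-fold). Of 22 colorectal markers, 19 were higher in DLD1 and 0 in LNCaP, among them CDX2 (at least 708-fold) and GPA33 (46.2-fold). Androgen response genes were higher in LNCaP in 23 of 29 cases, and immediate early genes in DLD1 in 29 of 33. These counts, from limma with tetracycline as a block, are over all genes, and adjusted over the list alone they were the same. In all, 2967 genes were higher in LNCaP and 2650 in DLD1 at 2-fold or more and an adjusted p below 0.05, of 14133 tested. With normexp and quantile normalization the counts were 1835 and 1812, and with no filter on dim probes 956 and 943.

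The largest differences in favour of LNCaP were CBS (log2 11.52 ± 0.19, SE), an enzyme of cysteine synthesis, the cancer-testis genes MAGEA2B (at least 2930-fold, above background on 1 of the 2 DLD1 arrays), MAGEA6 (at least 1309-fold) and CSAG1 (at least 931-fold), BNIP3 (at least 1964-fold), SPON2 (10.21 ± 0.18), FOLH1, PRAC1 (at least 1079-fold), MT1G (at least 955-fold) and ZG16B (at least 896-fold). In favour of DLD1 they were the detoxifying enzyme GSTP1 (at least 8306-fold), the lectin LGALS3 (at least 6530-fold), S100A10 (at least 5978-fold), S100A6 (at least 3658-fold), ANXA2 (log2 -11.42 ± 0.29), IER3 (-10.72 ± 0.23), TUBB6 (at least 1874-fold, above background on 1 of the 2 LNCaP arrays), the imprinted RNA H19 (-10.58 ± 0.44), FOXQ1 (-10.54 ± 0.30) and the growth factor AREG (at least 1168-fold). The adjusted p of limma's test was 7.28e-05 for H19 and at most 3.56e-05 for the others. With no filter on dim probes, 3 of them, ANXA2, FOXQ1 and H19, had adjusted p of 0.0521, 0.0566 and 0.0767 in limma. MAGEA, CSAG and MT1 genes have near-copies that probes may not tell apart. PYCARD averaged 2.96-fold higher in LNCaP (log2 1.56 ± 0.25, adjusted p of limma's test 0.00545). That average takes in the arrays with tetracycline, at log2 7.95 in LNCaP and 5.98 in DLD1, against 4.47 and 3.31 without it. The PYCARD signal does not separate a line's own gene from the placed one. The residual error of these fits is how far the tetracycline responses of the 2 lines differ, with 1 residual degree of freedom. Whether the arrays came from separate cultures is not stated beyond their labels.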

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

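Of the tests in this part, those of other probes and of neighbouring genes were set before their results were seen. The tests of clustered positions, of the PYDC1 signal, of tetracycline itself and of single cultures were chosen only after results were seen, as was the use of list medians and loess, both fixed settings, as tests of an explanation. The cell cycle list stood out because its median lay below the random range in LNCaP, at -0.49, and above it in DLD1, at 0.27, a difference of -0.76 that was not tested. NRF2 targets lay above the range in LNCaP, at 0.19, and below it in DLD1, at -0.17, a difference of 0.36 that was not tested and whose DLD1 side lay inside the random range under 4 alternatives.

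Many changed dim spots lay beside other changed dim spots. The lowest share with at least 2 changed neighbours, over both lines and both directions, was 23.2%, against at most 2.79% in 200 shuffles of the positions. Changed transcripts of the genes on those spots are argued against by 36 other probes of the same genes, whose median signed change was 0.11 (interval -0.07 to 0.17), where the clustered probes had a median size of 2.39. Light spread over neighbouring spots of an array is a candidate explanation, since it would give such clusters.

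PYDC1 was higher with tetracycline in both lines. If its probe bound a fixed share of all PYCARD transcript, LNCaP without tetracycline would have had more PYDC1 signal: the measured value was lower than predicted, at log2 -1.59 ± 0.19. Raised transcription across the locus is argued against by 7 measured neighbouring genes, among them BCKDK and KAT8, with a median of 0.13 ± 0.08 (SE) in LNCaP. A transcript made only from the construct and bound by the PYDC1 probe cannot be told apart from a rise of PYDC1 itself: the PYDC1 rise per PYCARD rise differed between the lines by log2 1.18 ± 0.23, but PYCARD was among the brightest probes and its signal may be compressed.

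Higher p53 targets in LNCaP and lower ATF4 targets in DLD1 were weighed together. A trend with spot brightness is argued against, since both medians lay outside all random lists matched on brightness. After loess the p53 median in LNCaP was 0.72 (random range -0.10 to 0.10). The ATF4 median in DLD1 was then -0.53 (random range -0.10 to 0.09). As the random lists were already matched on brightness, loess is no separate test. Tetracycline blocking mitochondrial translation would be expected to raise ATF4 targets, which their DLD1 median of -0.60 (random range -0.15 to 0.05), the pattern itself, argues against in that line alone, while for p53 targets in LNCaP it cannot be told apart from other explanations, as the ATF4 median there, -0.068, lay inside its range (-0.087 to 0.089). An effect of tetracycline itself cannot be told apart from one of PYCARD, because 0 arrays came from a line without the construct. The state of the single culture behind each array cannot be told apart from it either, with 1 array per group, and a response to PYCARD stays open as untested.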

How the results depend on the processing

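Most settings were fixed in advance, while the tests without clustered spots, counts within a line over genes above the median signal, and those with separate floors and with members above background on both arrays were chosen only after results were seen. No paired analysis was possible because the groups share only replicate number 1, other than by cell line, which was a block in the fit of the common effect. Leaving out a replicate was not applicable, and slide as a block was not run because 1 slide holds all 4 arrays. Precision is limited most for dim probes, near background. The cause was not tested for any change below, except where fewer genes, or another threshold, define the alternative. Genes past 2-fold in LNCaP (468) and DLD1 (406) numbered 81 and 87 with normexp and quantile normalization, 261 and 220 above background on every array, 1347 and 1416 at 1.5-fold, 200 and 179 at 3-fold and 28 and 30 above the median signal, and 825 in LNCaP with spike-in scaling. The correlation between lines was -0.0650 with normexp and quantile, -0.0354 with the mean of probes, -0.0544 above background on every array, -0.125 with no filter, -0.132 above the median signal and -0.0407 without clustered spots. The difference between lines counted 168 genes with normexp and quantile. The common effect had 1 call in limma with normexp and quantile, 396 at an unadjusted p and 5 with each array's own floor, trend and robust eBayes. LNCaP against DLD1 gave 3647 genes with normexp and quantile and 1899 with no filter. PYCARD stood at 3.34 with normexp and 3.35 with quantile in LNCaP, and at 2.79 and 2.83 in DLD1. Of 106 other log2 differences of genes named within a line, 103 moved by more than their spot error with normexp and quantile, all toward 0, with 59 under 2-fold against 11 as reported. With spike-in scaling 63 moved (31 toward 0) and with the mean of probes 24, all toward 0. Without clustered spots 49 had no value left and 6 of 57 moved. None changed direction, but genes whose direction changed with the choice of probe had been left out of the genes named. For the largest rises and falls, the naming rule also required every other measured probe to have the same direction. The mean of probes is therefore no check of direction. With normexp and quantile, list medians were 0.22 for NF-kB, -0.071 for interferon, -0.52 for ATF4, 0.17 for the unfolded protein response, 0.31 for heat shock and -0.088 for NRF2 in DLD1, and 0.54 for p53, -0.42 for cell cycle, 0.10 for NRF2, -0.11 for prostate and 0.15 for leukocyte markers in LNCaP. With quantile alone in DLD1 they were 0.32 for cell cycle, -0.53 for ATF4, 0.17 for the unfolded protein response, 0.32 for heat shock, -0.080 for NRF2 and -0.47 for colorectal markers. With loess in DLD1 they were -0.11 for interferon, -0.53 for ATF4, 0.17 for the unfolded protein response, 0.26 for heat shock and -0.065 for NRF2. List means in DLD1 were 0.40 for NF-kB, -0.11 for interferon, -0.73 for ATF4, 0.041 for the unfolded protein response, -0.10 for NRF2 and -0.18 for prostate markers, and in LNCaP 0.061 for the unfolded protein response, -0.21 for Wnt, 0.26 for NRF2 and 0.55 for leukocyte markers. Against unmatched lists the unfolded protein response, at 0.12 in LNCaP and 0.090 in DLD1, lay inside the random range. The p53, cell cycle, ATF4 and NF-kB lists named above kept their direction and stayed outside the random range under every alternative run. Spike-in scaling is no check here, since it moves all genes of a line alike and list values are relative to the median gene.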

Other observations

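Of the tests in this part, those of the DUX4 and BMP lists were set before the values of the members used had been seen, but both lists were chosen because other members stood out. SNAI2, also a member of a fixed list whose values had been looked at, was taken out of the BMP test after its first result, which lowered the median. The genes of the next paragraph were also picked after their values were seen.

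In LNCaP, several well-measured genes outside the fixed naming rule were higher with tetracycline: SEC14L2 (log2 2.19 ± 0.10), the calcium-binding protein S100P (2.18 ± 0.08), the growth factor-binding protein IGFBP3 (1.65 ± 0.02) and SERPINB5 (1.40 ± 0.10). S100P was lower in DLD1 (-0.83 ± 0.08) and IGFBP3 higher (0.97 ± 0.10). In DLD1, TSC22D3, a glucocorticoid-induced gene, was lower (-1.59 ± 0.09), as were the mitochondrial enzyme PCK2 (-1.41 ± 0.09) and the glycine transporter SLC6A9 (-1.30 ± 0.09), while the protease KLK7 (1.19 ± 0.10) and the protease inhibitor CST6 (1.27 ± 0.09) were higher.

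ZSCAN4 and PRAMEF genes, among the largest rises in LNCaP, are known targets of the early-embryo regulator DUX4, and a rise of the genes that DUX4 activates may account for them. Of 46 listed targets not seen before, 18 were measured in LNCaP, 12 were at least 1.5-fold higher and 0 lower, and their median was 1.75 (random range -0.15 to 0.22). Among them were MBD3L2, RFPL4B (2.27) and RFPL4A (2.05), while TRIM48 stood at 0.20. PRAMEF2, PRAMEF6, LEUTX (1.49 ± 0.40) and ARGFX (0.63 ± 0.44), also counted as higher, were above background on 1 array only, so their values are bounds. PRAMEF genes are near-copies, and without them the median was 0.51 over 11 genes (random range -0.19 to 0.27). In DLD1, 4 such genes were measured, with a median of 0.52 (random range -0.56 to 0.47).

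ID1 (1.29), ID2 (1.04) and SMAD6 (1.04), which BMP signalling induces, were higher in LNCaP, and a rise of BMP target genes may account for them. Of 18 listed targets not seen before, 10 were measured, 5 were at least 1.5-fold higher and 0 lower, and their median was 0.44 (random range -0.21 to 0.21). HEY1 (0.78), SMAD9 (0.71) and ID3 (0.61) were among them, while GATA2 stood at -0.26. In DLD1 the median of these targets was -0.01, inside the random range (-0.23 to 0.25). That of all 14 measured members was -0.25 (random range -0.20 to 0.18). These 14 add ID1 (-0.83), ID2 (-0.48), SMAD6 (-0.84) and ATOH8 (-1.46), whose values had been seen, so their median is no test. Neither hypothesis separates PYCARD from tetracycline.

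The 75th percentile lay below the centre of the spike-in probes by a different amount on each array, at log2 -1.84, -2.35, -2.44 and -2.31 for LNCaP without, LNCaP with, DLD1 without and DLD1 with tetracycline.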
